A study of Mus musculus with 6 samples.

How the data were processed

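Kidney endothelial cells were isolated from 6 mice by collagenase digestion and CD31 magnetic sorting, and libraries were sequenced as paired ends for 100 cycles, per the labels' protocols. The deposited file holds FPKM per gene for 55487 genes in 6 libraries, which the authors normalized to fragments and gene length. Per the submitters' processing notes, DESeq2 was used and the genome builds named were mm10 and GRCm38. The aligner, counter and strand setting are not given in the sources used here. Gene coordinates are those of the deposited file, and 55227 of its gene IDs are in GENCODE M21 (54907 with the same coordinates).

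FPKM multiplied by exon length gave whole fragments for 98.5 to 98.6% of values under 1000 fragments, within 0.05 of a whole number. These recovered fragments gave library totals of 834149 to 16954486. Because the unit is FPKM, no count model was the main test and the planned count-model fits were not run. Limma-voom on recovered fragments was run as an alternative instead.

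Samples were grouped by the labels into 3 control and 3 I-PpoI mice, and the labels describe separate mice. Limma was fitted to log2(FPKM + 1) for genes with a mean of at least 1 FPKM, without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of low genes. Lists of at least 5 measured members were tested with camera at a preset correlation of 0.01, of 44 lists fixed before the data were examined, and adjusted over lists. The tools were R 4.3.3, limma 3.58.1, python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

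Genes named in the text follow a rule set before the data were examined. It takes up to 12 genes per direction past the threshold with groups that do not overlap, or, where fewer than 5 pass, the 8 of smallest p. It skips clone names, pseudogenes, Y-linked genes and Xist, and adds endothelin members, Cdh5, Pecam1, Trp53, Cdkn1a and Cdkn2a. It also adds up to 4 members of each list past the threshold and up to 2 of each list not past it. A gene that the rule takes is not reported here. Sex-linked genes, mt-Nd6, Lrp2 and the few genes called under single alternatives were named after their values were seen.

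The FPKM of I-PpoI mice 1 and 2 showed most mitochondrial fragments on the minus strand, and so a strand-clear set of 3654 tested genes was defined after the data were seen. Any gene with a neighbour on the opposite strand can hold fragments of that neighbour in these libraries. FPKM of these 2 libraries is also scaled by few counted fragments. Strand-clear genes held 241106 and 79921 recovered fragments in I-PpoI mice 1 and 2. They held 2333462 in I-PpoI mouse 3 and 4057312 to 5017751 in the controls. If these 2 libraries were counted on the opposite strand, strand-clear genes would hold only the fragments left on their annotated strand. Strand-clear values in I-PpoI mice 1 and 2 are therefore uncertain too.

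The replicate numbers were checked as pairs by the correlation of deviations from group means. Same-numbered libraries correlated at 0.26, 0.20 and 0.19 over the strand-clear genes, so the blocked value is given beside that result. The pairing comes from these correlations, and the labels do not say that a number marks a shared litter or day.

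The limma step was tested on simulated data with 200 changed genes. All 6 libraries were drawn from the control mean profile with a dispersion of 0.05. At the deposited library totals limma recovered 10.8% of 2-fold and 78.9% of 4-fold changes over 12908 genes. Over 3722 strand-clear genes it recovered 32.3% and 99.0%. It called 15 and 7 unchanged genes. The simulation held no strand shift and no mitochondrial or tubule rise, so these rates need not hold for the deposited libraries. The alternatives covered pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, other scalings, robust and weighted fits, the replicate block, protein-coding genes, each library left out, camera with an estimated correlation, and fry. Shares of single libraries have 95% exact Clopper-Pearson intervals, and a count of 0 was read as allowing 3 fragments.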

Results

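RNA of kidney endothelial cells was measured in 6 mice fed a high-fat diet, with 60% of its energy from fat, for 4 weeks from 8 weeks of age. In the I-PpoI group, 3 mice carried a VE-cadherin-driven Cre recombinase together with a Cre-dependent I-PpoI gene, at a Rosa locus whose number differs between the genotype labels of the 3 mice. I-PpoI is a homing endonuclease that makes DNA double-strand breaks, and VE-cadherin (Cdh5) is an endothelial adhesion protein, so the cut is aimed at endothelium. The control group was 3 wild-type littermates. Cells were taken from digested whole kidneys with magnetic beads against CD31 (Pecam1). The series concerns endothelial DNA damage and the endothelin-1 and endothelin A receptor pathway.

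The libraries differed in depth and in strand. Whole fragments recovered from the FPKM values came to 16158353, 14081223 and 16954486 in control mice 1, 2 and 3, and to 1590957, 834149 and 13324313 in I-PpoI mice 1, 2 and 3. Antisense gene models, which lie across from another gene, took 14.7% of fragments in I-PpoI mouse 1 (95% exact Clopper-Pearson interval 14.7 to 14.8%) and 10.02% in I-PpoI mouse 2 (9.95 to 10.1%). The share was 0.119% in I-PpoI mouse 3 and 0.197 to 0.225% in the controls. Of mitochondrial fragments, 68.2% (67.9 to 68.5%) and 70.6% (70.5 to 70.8%) lay on minus-strand genes in I-PpoI mice 1 and 2, against 0.0821% in I-PpoI mouse 3 and 0.0473 to 0.0664% in the controls. The minus-strand gene mt-Nd6 stood at 65124 and 372886 FPKM in I-PpoI mice 1 and 2 and at 668 FPKM in I-PpoI mouse 3. These intervals cover counting error only.

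**Figure D1:**
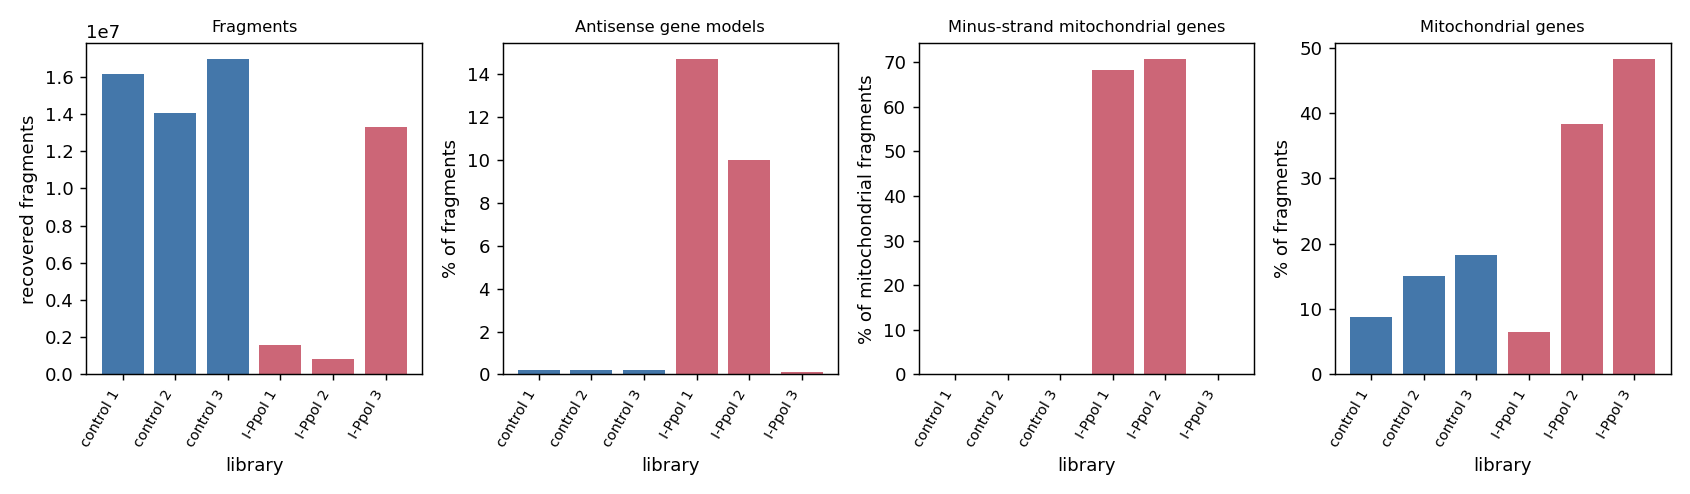
Bars give, for each of the 6 libraries, the recovered fragments, the percent of fragments on antisense gene models, the percent of mitochondrial fragments on minus-strand genes, and the percent of fragments on mitochondrial genes; blue is control and red is I-PpoI. I-PpoI mice 1 and 2 have the fewest fragments and the highest antisense (14.7% and 10.02%) and minus-strand shares (68.2% and 70.6%).

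Sex-linked transcripts also differed between the groups. The Y-linked gene Ddx3y had 1488, 959 and 1672 fragments in control mice 1, 2 and 3, 20 in I-PpoI mouse 1, and 0 in I-PpoI mice 2 and 3. The X-inactivation transcript Xist had 4, 0 and 0 fragments in the controls, 0 in I-PpoI mouse 1, and 70 and 4739 in I-PpoI mice 2 and 3. A count of 0 allows up to 3 fragments of the 834149 in I-PpoI mouse 2 and of the 13324313 in I-PpoI mouse 3. By these transcripts 4 libraries were male, 3 of them control, and 2 were female, both I-PpoI.

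Mitochondrial genes took 8.83%, 15.1% and 18.3% of fragments in control mice 1, 2 and 3, and 6.42%, 38.2% and 48.2% in I-PpoI mice 1, 2 and 3. Lrp2, the megalin receptor of the proximal tubule, was at 2.33, 3.65 and 3.12 FPKM in the controls and at 0.784, 14.3 and 66.5 FPKM in the I-PpoI mice.

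The first comparison asked which genes differed between the CD31-sorted kidney cells of I-PpoI and control mice, whatever cells these held. No gene passed. The 8 genes of smallest p in each direction, none past the threshold, were taken by p alone. On the higher side, Slc3a1, a subunit of a dibasic amino acid transporter, was at 43.6 ± 17.9 FPKM in I-PpoI and 4.997 ± 1.69 in control (SD, n = 3 each). Fam151a was at 35.8 ± 6.35 against 5.51 ± 2.61 FPKM, and Slc23a1, a vitamin C transporter, at 6.50 ± 1.62 against 0.961 ± 0.0804 FPKM. The others were Slc39a5, Car14, mt-Tr, mt-Nd3 and Apom. On the lower side, Sumo2 was at 3.01 ± 0.944 against 22.2 ± 8.11 FPKM and Rergl at 4.27 ± 1.69 against 30.1 ± 9.25 FPKM. Others were Igkj5, Kcne3, Wfdc1, Cdk19 and Mir1932. Each of these named genes had limma adjusted p = 0.124. Slc3a1, Fam151a, Car14, Kcne3 and Cdk19 have an exon of another gene on the opposite strand, and Slc23a1, Slc39a5, mt-Tr, mt-Nd3, Apom and Wfdc1 have such a gene within 5 kb. Their values in I-PpoI mice 1 and 2 are uncertain.

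Of 14962 genes with a mean of at least 1 FPKM, limma called 0 at adjusted p under 0.05, with 5503 at unadjusted p under 0.05, of which 646 were higher and 4857 lower; with median-of-ratios scaling, which called 0, there were 1373, of which 873 were higher and 500 lower. The median log2 fold change over these genes was -0.65, on the log2(FPKM + 1) scale, so lower values are relative to that shift. With limma-voom on recovered fragments, chosen after the data were seen, 0 genes passed and 528 had unadjusted p under 0.05 (373 higher and 155 lower). Rescaling each library to a common total called 903 genes higher and 4511 lower, and leaving out I-PpoI mouse 3 called 2965 higher and 5509 lower; without I-PpoI mice 1 and 2, which leaves 1 I-PpoI library assumed to vary like the controls, 22 were higher and 0 lower.

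The second comparison concerned the endothelin system, the vasoconstrictor peptides with their receptors and processing enzymes. Edn1, which encodes endothelin-1 (ENSMUSG00000021367, GRCm38 chromosome 13, 42301476 to 42307990), was at 14.9 ± 0.558 FPKM in I-PpoI and 39.9 ± 8.66 in control (SD, n = 3 each). Ednrb, the endothelin B receptor (chromosome 14, 103814625 to 103844402), was at 8.10 ± 7.53 against 31.8 ± 5.62 FPKM. Ednra, the endothelin A receptor (chromosome 8, 77663031 to 77724464), was at 1.63 ± 0.771 against 4.10 ± 1.77 FPKM, and Ece1, the converting enzyme (chromosome 4, 137862237 to 137965229), at 51.2 ± 24.9 against 111 ± 10.03 FPKM. Edn3 was at 1.40 ± 1.14 against 2.64 ± 0.969 FPKM and the peptidase Mme at 3.01 ± 3.02 against 4.17 ± 1.75 FPKM. Edn2 and Kel were listed at 0 in every library and Ece2 was near 0.

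Over all genes, 0 of the 6 endothelin members tested passed (limma adjusted p = 0.124 for Edn1 and Ednrb, 0.125 for Ece1 and 0.135 for Ednra). Adjusted over the list alone, 2 of 6 were lower, Edn1 (log2 fold change -1.34, SE 0.29, adjusted p = 0.0180 by limma) and Ednrb (-2.20, SE 0.64, adjusted p = 0.0380 by limma). An exact two-sided permutation test of Edn1 gave p = 0.10, the smallest that 3 against 3 allows. As a list the members did not pass (camera adjusted p = 0.151), and with median-of-ratios scaling of the strand-clear genes described next, Ednrb was at -1.18 (SE 0.45, adjusted p = 0.488 by limma) and Ece1 at -0.07. Edn1 and Ednra have an exon of another gene on the opposite strand and were outside that set. Of the 4 endothelin members tested in it, 0 passed adjusted over the list alone. Relative to the median of 15 strand-clear endothelial genes, Edn1 differed by 0.49 on the log2 scale (exact permutation p = 0.40). The values were -0.95, -0.86 and -1.38 in control mice 1, 2 and 3 and -0.85, 0.50 and -1.37 in I-PpoI mice 1, 2 and 3; without I-PpoI mouse 2 the difference was -0.05.

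**Figure D2:**
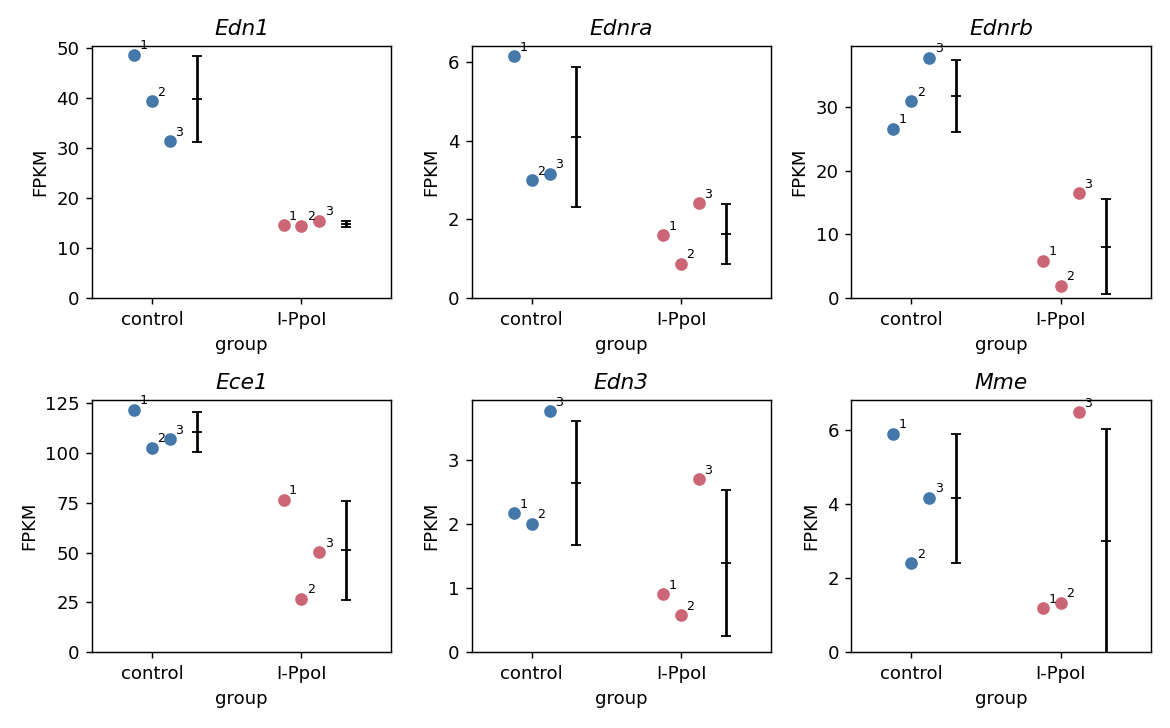
Points give deposited FPKM of 6 endothelin genes in each library, numbered by mouse, with control in blue and I-PpoI in red; bars are the mean ± SD of 3 mice. Edn1 lies at 14.5 to 15.5 FPKM in the I-PpoI mice and at 31.4 to 48.8 FPKM in the controls.

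The third comparison concerned gene lists. Of 41 lists tested over all genes with camera, 15 passed, 12 of them lower and 3 higher relative to other genes. None of the 15 passed with an estimated correlation (adjusted p = 0.691 with an estimated correlation for each). Endothelial identity genes fell as a list (adjusted p = 0.00116; median log2 fold change -1.41), with 26 of 26 below 0, 0 past over all genes and 20 lower adjusted over the list alone. Cd34, a surface sialomucin, was at 19.8 ± 14.0 against 81.6 ± 13.6 FPKM and the junction protein Esam at 61.6 ± 23.1 against 186 ± 28.6 FPKM (SD, n = 3 each). Of the checks named beforehand, Cdh5 was at 138 ± 67.7 against 307 ± 35.3 FPKM and Pecam1 at 86.4 ± 39.1 against 230 ± 29.98 FPKM, neither past the threshold. Arterial genes fell likewise (adjusted p = 0.00106, with 16 of 18 lower adjusted over the list alone). So did descending vasa recta genes (0.0309, 10 of 12), angiogenesis genes (0.0173, 11 of 22) and coagulation genes (0.0309, 10 of 14). These member counts are for FPKM as deposited, beside the shift of all genes. Over strand-clear genes scaled by median of ratios, 0 members of each of these lists passed adjusted over the list alone. Mitochondrial fragments made up 38.2% and 48.2% of I-PpoI libraries 2 and 3, beside these lists.

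Interferon-stimulated genes also fell (adjusted p = 0.00560; adjusted p = 0.691 with an estimated correlation), with 33 of 33 below 0 and 0 past adjusted over the list alone. The antiviral gene Rsad2 was at 15.1 ± 13.5 against 63.0 ± 4.20 FPKM (SD, n = 3 each). Ribosomal protein genes (0.00286), nuclear oxidative phosphorylation genes (0.0309), fatty acid genes (0.0409), leukocyte adhesion genes (0.0476), nucleolar genes (0.0343) and lymphocyte genes (0.0309) fell by camera adjusted p as well, each with adjusted p = 0.691 with an estimated correlation. Adjusted over the list alone, 6 of 12 lymphocyte genes were lower and 0 of the other 5 lists' members. Mitochondrially encoded genes (0.0309), proximal tubule genes (0.0334) and macrophage genes (0.0424) rose as lists relative to other genes. Each again had adjusted p = 0.691 with an estimated correlation. Of their members, 7 of 13, 17 of 24 and 8 of 15 were above 0. In I-PpoI mouse 1 the list medians lay at -2.66, -1.21 and -0.75 from the control mean. Each call was lost by fry, with median-of-ratios scaling, without I-PpoI mouse 3 and without control mouse 1.

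Targets of p53, the damage-response transcription factor, did not pass as a list (camera adjusted p = 0.0826), with 25 of 30 below 0 beside the shift of all genes. Trp53 itself was at 8.42 ± 3.46 against 17.3 ± 2.04 FPKM and its target Cdkn1a at 9.77 ± 4.95 against 22.0 ± 5.23 FPKM as deposited (SD, n = 3 each). Scaled by median of ratios, the groups overlapped: log2 values were 3.98, 3.39 and 3.64 against 3.46, 3.85 and 3.63 for Trp53, and 3.94, 3.47 and 4.08 against 3.49, 4.07 and 4.30 for Cdkn1a. DNA break repair genes (0.688), senescence genes (0.331) and cell cycle genes (0.861) did not pass by camera adjusted p. Cdkn2a was below the filter, at 0.361 ± 0.570 against 0.174 ± 0.121 FPKM.

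A second set of results, chosen after the data were seen, used strand-clear genes, which are nuclear protein-coding genes with no gene on the opposite strand within 5 kb of an exon. Of 3654 such genes, scaled by median of ratios, limma called 0, with 355 at unadjusted p under 0.05 (161 higher and 194 lower), and limma-voom called 0 with 260 (203 higher and 57 lower). The replicate block called 3, Mt1 higher and Ddx3y and Eif2s3y lower. Leaving out I-PpoI mouse 3 called 356 and leaving out I-PpoI mouse 1 called 30. In I-PpoI mice 1 and 2 the strand-clear genes rest on 241106 and 79921 recovered fragments.

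In the strand-clear genes, camera called 7 of 32 lists, each with adjusted p = 0.733 with an estimated correlation. Arterial genes (adjusted p = 0.0161), descending vasa recta genes (0.0290) and interferon-stimulated genes (0.0408) fell. Alox12 was at 6.60 ± 3.40 against 26.3 ± 0.800 FPKM as deposited (SD, n = 3 each). Fibroblast genes (0.0144), macrophage genes (0.0144), proximal tubule genes (0.0375) and complement genes (0.0375) rose. Macrophage, proximal tubule and complement calls were lost without control mouse 1 and without I-PpoI mouse 3, and the last 2 also without I-PpoI mouse 2. Fibroblast and arterial calls were lost without I-PpoI mouse 3. Descending vasa recta calls were lost without control mouse 2, I-PpoI mouse 1 or I-PpoI mouse 3, and interferon calls without control mouse 3, I-PpoI mouse 1 or I-PpoI mouse 2. The phosphoenolpyruvate carboxykinase gene Pck1 was at 170 ± 122 against 63.8 ± 18.9 FPKM and the lipoprotein gene Apoe at 164 ± 94.5 against 86.6 ± 24.5 FPKM. Endothelial identity genes did not pass (0.0865; median -0.35), nor did p53 targets (0.689; 7 of 14 above 0, median -0.02). Ribosomal protein genes (18 of 20 above 0, median 0.21) and leukocyte adhesion genes (6 of 9 above 0, median 0.08) did not pass. They lay on the other side from the all-gene lists, as did 3 of 4 nuclear oxidative phosphorylation genes. The all-gene lists used FPKM as deposited, without this scaling. The median log2 fold change over strand-clear genes was -0.92 as deposited and -0.03 scaled, so scaling can turn such signs. The proximal tubule median was 2.17 and 2.59 above control in I-PpoI mice 3 and 2 and -0.42 in I-PpoI mouse 1.

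**Figure D3:**
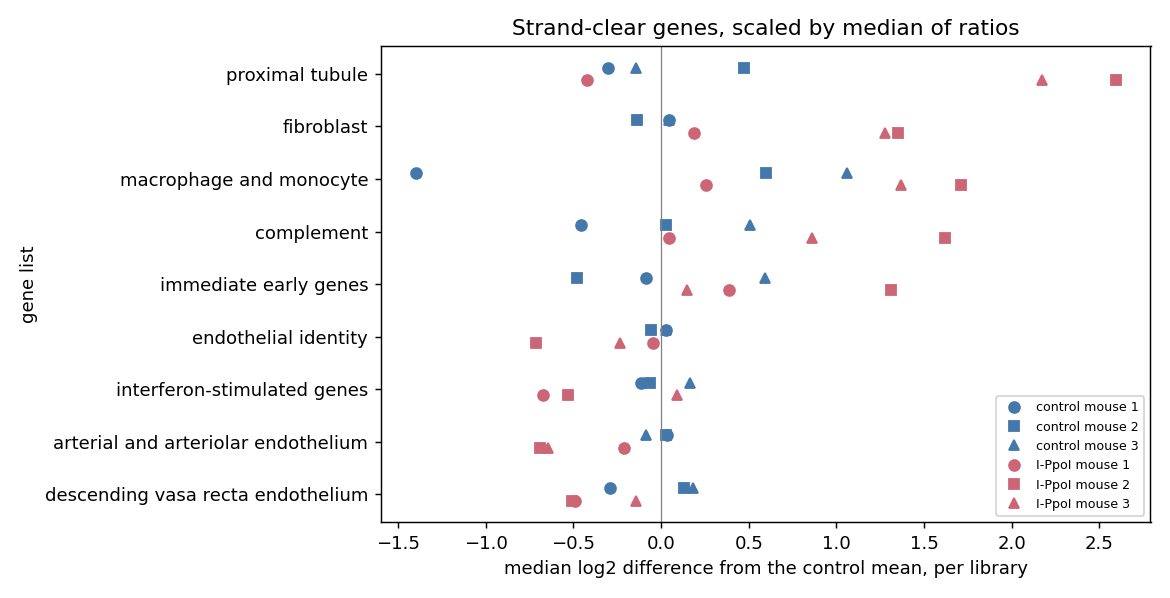
Points give the median log2 difference from the control mean over the strand-clear members of each gene list with camera adjusted p under 0.1, in each library, with control in blue and I-PpoI in red and 1 marker shape per mouse number. Proximal tubule medians lie at 2.17 and 2.59 in I-PpoI mice 3 and 2 and at -0.42 in I-PpoI mouse 1.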

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

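Limma-voom, the strand-clear set with its own alternatives, and fits without I-PpoI mice 1 and 2 or with male mice only were chosen after the data were seen; the other alternatives were planned. The all-gene count of 0 held for both other pseudocounts, no filter, 5 FPKM, median-of-ratios and quantile scaling, robust fits, the replicate block, protein-coding genes and limma-voom. At adjusted p under 0.1 the main fit also called 0, but protein-coding genes only called 5612 and 5 FPKM called 1803. With protein-coding genes only, the smallest limma adjusted p was 0.0525. It became 5414 (903 higher, 4511 lower) rescaled to a common total, 6829 (2784 higher, 4045 lower) with array weights, 1440 (13 higher, 1427 lower) over strand-clear genes as deposited, and 22 (22 higher) without I-PpoI mice 1 and 2, where 1 I-PpoI library is assumed to vary like the controls. Leaving out 1 library gave 0 to 8474 genes (0 to 2965 higher, 0 to 5509 lower), with every call from leaving out I-PpoI mouse 3. Endothelin genes past the threshold were 3 rescaled to a common total, 2 with array weights, 2 over strand-clear genes as deposited, and 0 to 5 with 1 library left out.

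The 15 gene lists became 0 with an estimated correlation, 26 by fry, 30 by fry for either direction, 9 at 5 FPKM, 7 with median-of-ratios scaling, 7 rescaled to a common total, 7 with array weights, 7 over strand-clear genes as deposited, and 8 without I-PpoI mice 1 and 2, again with 1 I-PpoI library. With 1 library left out they were 2 to 14, lowest without I-PpoI mouse 3. The replicate block of all genes left 0 genes, and same-numbered libraries correlated at 0.09, 0.06 and -0.02 there.

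For strand-clear genes, the count of 0 became 1 (1 lower, Eif2s3y) at adjusted p under 0.1, 1440 (13 higher, 1427 lower) as deposited, 3 (2 higher, 1 lower) when only exon overlap was excluded, 3 (1 higher, 2 lower) with the replicate block, 42 (40 higher, 2 lower) without I-PpoI mice 1 and 2, and 630 (238 higher, 392 lower) with male mice only, where a lone I-PpoI library is assumed to vary like the controls. Leaving out 1 library gave 0 to 356 (0 to 144 higher, 0 to 212 lower). Its 7 lists became 0 with an estimated correlation, 0 by fry, 1 by fry for either direction and 0 with male mice only, and were 1 to 8 with 1 library left out, lowest without I-PpoI mouse 3. The block changed single list calls: leukocyte adhesion was lost and basement membrane gained over all genes, and antigen presentation gained over strand-clear genes.

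Direction turned for some lists. Without I-PpoI mice 1 and 2 the all-gene medians were -0.63 for fatty acid genes, -0.52 for nuclear oxidative phosphorylation and -0.24 for NRF2 targets, and camera's direction against other genes was up. The gene list antioxidant and NRF2 targets then passed, with camera adjusted p = 0.00546, on 1 I-PpoI library. The proximal tubule median was -0.34 to 1.11 with 1 library left out, lowest without I-PpoI mouse 3. In strand-clear genes the interferon median was 0.11 without I-PpoI mice 1 and 2, and with male mice only the medians were 0.069 for complement and -0.47 for proximal tubule. The cause was not tested. The depth of I-PpoI mice 1 and 2 limits low genes.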

Other observations

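All tests in this part were chosen after the results they bear on were seen. Over strand-clear genes scaled by median of ratios, neither p53 targets (7 above 0 and 7 below) nor unfolded protein and integrated stress response genes (3 above 0 and 4 below, median -0.23) passed as a list. Of members named by the rule for lists, Gdf15, a stress-induced cytokine, was at a log2 fold change of 1.28 (SE 0.39) and Sesn2, a p53 target, at 1.00 (SE 0.33), each with adjusted p = 0.488. As deposited, Gdf15 was at 20.0 ± 2.20 against 18.4 ± 7.53 FPKM (SD, n = 3 each). Collecting duct (camera adjusted p = 0.306) and glycolysis genes (0.169) did not pass.

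Antisense gene models and minus-strand mitochondrial genes were high in I-PpoI mice 1 and 2. Counting error at low depth is argued against. Control libraries thinned to these totals reached at most 0.236% of fragments on antisense models, against 10.02% observed. Thinning leaves a share unchanged apart from that error, so it tests no other effect of low depth. A first test of opposite-strand counting, the rank correlation of an antisense model with its host gene across genes, was set to count against it unless higher than elsewhere; it was 0.480, below the 0.552 of a control. It lay within 0.1 in all 6 libraries, so it was judged uninformative after its value was seen, and a second test was added. At least 62.3% of 1139 pairs had more antisense than host fragments in I-PpoI mice 1 and 2, against at most 0.439% elsewhere. Fragments assigned to the opposite strand would give this, but so could a rise of antisense RNA. The second test largely restates the pattern and cannot decide between them. Over 5764 genes with an opposite-strand exon, I-PpoI mice 1 and 2 correlated with the controls at 0.010 to 0.075 (Pearson). I-PpoI mouse 3 correlated with them at 0.950 to 0.962. These values argue against a rise of antisense RNA that left sense RNA the larger part in I-PpoI mice 1 and 2. A rise beyond sense RNA would give the same pattern as opposite-strand counting. It stays open for these mice, although I-PpoI mouse 3 had 0.119% of fragments on antisense models.

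Proximal tubule and mitochondrial RNA were high in I-PpoI mice 2 and 3. Opposite-strand counting is argued against in mouse 3, whose strand-clear tubule median was 2.17 above control, and its test could not decide in mouse 2, at 2.59; I-PpoI mouse 1, with the same strand shift, was at -0.42. More tubule RNA in these libraries is a candidate explanation that the test left open. Of strand-clear tubule genes, 72.7% (8 of 11) were above every control in both, under the 75% set for it. The genes that were not were Kap, Slc7a13 and Aqp1, and Aqp1 is also on the descending vasa recta list. Lrp2 reached 66.5 FPKM in I-PpoI mouse 3. CD31 sorting should remove tubule cells, but sorted cells can carry some. Sex of the mice cannot be told apart, because 0 control libraries were female.

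As deposited, Edn1 FPKM was lower in all 3 I-PpoI libraries. Relative to 15 strand-clear endothelial genes the difference was 0.49 on the log2 scale, against -1.40 before (exact permutation p = 0.40, n = 3), and -0.05 without I-PpoI mouse 2. By its first rule this counted for a smaller endothelial share of RNA. Scaling over all strand-clear genes, however, put log2 Edn1 at 4.39, 4.96 and 4.08 in I-PpoI mice 1, 2 and 3. The controls lay at 4.46 to 4.93, so I-PpoI mouse 2 was above every control. That scaling also left a difference of only -0.24 (exact permutation p = 0.50), and -0.48 without I-PpoI mouse 2. The test relative to endothelial genes was therefore judged unable to decide, after its value was seen. I-PpoI mice 1, 2 and 3 had endothelial shares of 2.98%, 1.66% and 2.62% of strand-clear fragments, against 3.16 to 3.34% in the controls. Opposite-strand counting is argued against in mouse 3, where Edn1 was at 15.5 FPKM, below the lowest control at 31.4, and stays open in mice 1 and 2, where the lower value was 14.5 FPKM, as does an effect of I-PpoI on Edn1.

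Other splits of the 6 libraries cannot give a share under 0.05, since there are 10. For genes past the threshold the real count was 0 and the highest other 0 (10 of 10 splits as large), over all genes and over strand-clear genes alike. For gene lists the real count was 15 and the highest other 19 over all genes (3 of 10 splits as large), and 7 and 8 over strand-clear genes (5 of 10).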
